A study of Mus musculus with 9 samples.

How the data were processed

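RNA-seq was carried out on E14 mouse embryonic stem cells that were wild type (WT) or knockout (KO) for Hbxip, in pluripotent culture, after 96 h without LIF (day 4) and as embryoid bodies. Per the labels' protocols, total RNA was extracted with an RNeasy Mini Kit and libraries were prepared with standard Illumina protocols. Each condition held 1 WT and 2 KO libraries, and groups and replicate numbers were taken from the labels. Reads were aligned with Bowtie2 to mouse build mm8, per the submitters' processing notes. The quantifier, the strandedness and the annotation version were not given in the sources used here. Each deposited table holds 1 library and gives, per the file headers, an expected count (an estimated count, which need not be whole) and an FPKM value for each gene, with a gene length. Of the deposited expected counts, 78.0% to 78.4% per library lay within 0.005 of a whole number, and genes with a count of 0 were not listed. The FPKM values were made by the authors, per the file headers, and this unit scales by gene length and library size.

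Expected counts were rounded to whole numbers, and genes not listed in a library were set to 0 there. Of 20287 gene IDs listed in at least 1 library, 20234 were matched by gene ID and 9 by RefSeq accession to the RefSeq gene table of GRCm38, which was used only for names, so no coordinates are given. The other 44 kept their IDs. Totals per library ran from 10147277 to 10863845 rounded counts, a ratio of 1.07, and the 10 most counted genes held 5.42% to 6.16% of a library. At these totals 3 counts are worth 0.276 to 0.296 CPM. A gene with no count in 1 group is given as at least a fold, against 3 counts over the group. A gene with 1 to 3 counts in a group is given as a ratio with a 95% exact binomial counting interval.

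The planned test was limma on log2(FPKM + 1). Since the tables also hold estimated counts, edgeR's quasi-likelihood test on the rounded counts was used in its place, and the limma fit was kept as an alternative. Genes with a mean FPKM of at least 0.5 over the 9 libraries were tested, 13990 in all, with TMM factors between 0.94 and 1.04. The 9 comparisons within a condition or genotype, or between responses, came from 1 fit with a mean for each of the 6 groups. Its 3 residual degrees of freedom come from the 3 KO pairs, and its biological coefficient of variation was 6.52%. KO versus WT over the 3 conditions came from an additive fit of condition and genotype, with 5 residual degrees of freedom and a coefficient of variation of 18.1%. That spread pools how the genotype difference varied between conditions with the smaller spread within the 3 KO pairs. Its p-values can therefore be too small for a difference set against the variation between conditions alone. A gene's adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment within a comparison, and a gene was called where it lay below 0.05. Standard errors are the size of the log2 fold change over the square root of the test's F. They are not fitted errors of the fold change and can lie below the counting error where a group holds few counts. The KO pairs differed by more than counting noise, with a chi-square per degree of freedom of 3.4 in pluripotent culture, 4.72 after LIF withdrawal and 3.09 in embryoid bodies. No pair was therefore taken for copies of 1 library, which does not show that its libraries came from separate cultures, and the WT libraries had no pair to compare.

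A total of 27 gene lists was tested with camera in each of the 10 comparisons. They were Ragulator and Rag GTPase genes, naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, mesoderm and cardiac, blood and endothelium, definitive endoderm, extraembryonic endoderm, neuroectoderm, trophoblast, 2-cell-like state, fibroblast and feeder cells, glycolysis, hypoxia response, cholesterol biosynthesis and uptake, integrated stress response (ATF4 targets), lysosome and v-ATPase (TFEB targets), autophagy and FLCN-FNIP, mTOR pathway components, ribosomal proteins (with elongation factors), nucleolar and MYC-driven genes, p53 targets, cell cycle, NF-kB targets, imprinted genes and Y-linked genes. Hbxip was left out of its own list. A list's adjusted p is camera's, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 270 list tests. Camera was also run with an estimated correlation. A list's median is the median log2 fold change of its tested genes. The median of the primitive streak list is also given with its low-count genes at their bounds, or without them for a difference between responses.

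Named genes were, per comparison, the 6 largest rises and the 6 largest falls among called genes with a mean FPKM of at least 1 and a gene symbol that is not a clone, predicted or RIKEN name. They had to lie on the same side of WT in both KO libraries, or in 2 against 2 libraries not to overlap. From each list up to 4 members with the smallest p were added, and Hbxip was given in every library. The text gives part of these, and any gene outside the rule is marked. The comparisons, lists, naming rule and most alternatives were set before the data were examined.

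The alternatives were no filter on low values, a mean FPKM of at least 2, median-ratio scaling, limma on log2(FPKM + 1) and log2(FPKM + 0.1), limma on quantile-normalized log2(FPKM + 1), which is meant wherever quantile normalization is named, the replicate number as a block or a random effect, each library left out in turn, DESeq2, corrections for gene length with and without GC content, and the pluripotent libraries left out. A WT library was left out only for genes in KO versus WT over the 3 conditions, and lists were tested only with KO libraries left out. GC content was taken from the longest GENCODE M21 transcript, which gave a value for 99.1% of the tested genes. DESeq2, the corrections, the fit without the pluripotent libraries and the use of the planned limma fit as an alternative, for genes and for lists, were chosen after seeing the data. Other splits of the libraries were fitted for every choice of 3 libraries in the place of WT that could be estimated.

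The tests were tested on simulated data, drawn from the real means and library sizes of 13990 genes with 200 genes changed. For KO versus WT over the 3 conditions, 14.9% of genes changed 1.5-fold, 60.9% changed 2-fold and 91.3% changed 4-fold were called, with 11 calls among 13762 unchanged genes. In pluripotent culture these shares were 50.0%, 63.8% and 90.0%, after LIF withdrawal 38.7%, 69.1% and 97.1%, and in embryoid bodies 48.4%, 70.8% and 92.2%. For LIF withdrawal they were 37.3%, 69.2% and 97.1% in WT, 66.7%, 81.2% and 94.0% in KO, and 13.5%, 56.5% and 77.2% for the difference. For embryoid bodies they were 33.8%, 65.6% and 85.5% in WT, 50.0%, 77.8% and 89.3% in KO, and 23.1%, 48.0% and 76.7% for the difference. A simulated list of 28 genes changed 1.5-fold was called in each of the 10 comparisons, and 0 of the 26 other lists in any. Each gene was drawn independently, so the simulated lists held no correlation between genes. They cannot show whether the preset correlation suits the real lists. Their p-values were adjusted over the 27 lists of 1 comparison and not over all 270 list tests. Every simulated library was drawn independently, with the same spread for WT and KO. The calls among unchanged genes therefore do not test whether the WT libraries vary like the KO pairs, or whether the real libraries are independent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.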

Results

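Gene expression was measured by RNA-seq in E14 cells, a mouse embryonic stem cell line of strain 129, that were wild type (WT) or knockout (KO) for Hbxip, now named Lamtor5. The protein is a subunit of Ragulator, which holds the Rag GTPases at the lysosome surface and takes part in the activation of mTORC1 by amino acids. Cells were taken from pluripotent culture, on day 4 after 96 h without LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated, and as embryoid bodies, aggregates in which these cells begin to differentiate. Each of the 3 conditions held 1 WT library and 2 KO libraries, which made 9 libraries in 6 groups. Rounded counts summed to between 10147277 and 10863845 per library. At these depths 3 counts, the most that an observed count of 0 allows, correspond to 0.276 to 0.296 CPM. The labels do not say whether the libraries came from separate cultures or clones, so the p-values measure only the spread between these libraries. The 1 WT library of each condition was assumed to vary like the KO pairs. Intervals and limits for low counts cover counting error only. Values after ± are standard errors derived from the test's F, which can lie below the counting error where a group holds few counts. A gene's change is given as a log2 fold change. The first principal component of the log2 CPM values carried 51.8% of the variance. It set the KO pluripotent libraries, at 71.4 and 62.5, apart from the other libraries, which lay between -53.1 and 8.2.

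Hbxip itself was at 40.7 FPKM in WT pluripotent cells, 38.5 FPKM in WT cells after LIF withdrawal and 41.8 FPKM in WT embryoid bodies. In the KO libraries its level was 31.0 and 29.1 FPKM in pluripotent culture, 16.2 and 15.5 FPKM after LIF withdrawal, and 23.0 and 18.3 FPKM in embryoid bodies. The change from WT to KO was -0.32 ± 0.15 in pluripotent culture and did not pass the threshold (adjusted p = 0.0971). After LIF withdrawal Hbxip fell in KO, with -1.22 ± 0.16 (adjusted p = 7.49e-05), as it did in embryoid bodies, with -1.02 ± 0.15 (adjusted p = 0.000252). Over the 3 conditions the change was -0.86 ± 0.17 (adjusted p = 0.00589). From pluripotent culture to LIF withdrawal it was -0.05 ± 0.17 in WT (adjusted p = 0.865) and -0.96 ± 0.14 in KO (adjusted p = 7.31e-05). These responses differed by -0.91 ± 0.22 (adjusted p = 0.00785), a call that DESeq2 did not make. For embryoid bodies the responses differed by -0.71 ± 0.22 (adjusted p = 0.0199). That call was lost with DESeq2, limma on FPKM or a length correction. It was also lost without KO pluripotent replicate 1, at -0.65, and without KO embryoid body replicate 2, at -0.56. The values are per gene and do not show which part of Hbxip was targeted. Reads of Hbxip remained in every KO library, so these values do not establish the knockout, which is taken from the labels.

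**Figure D1:**
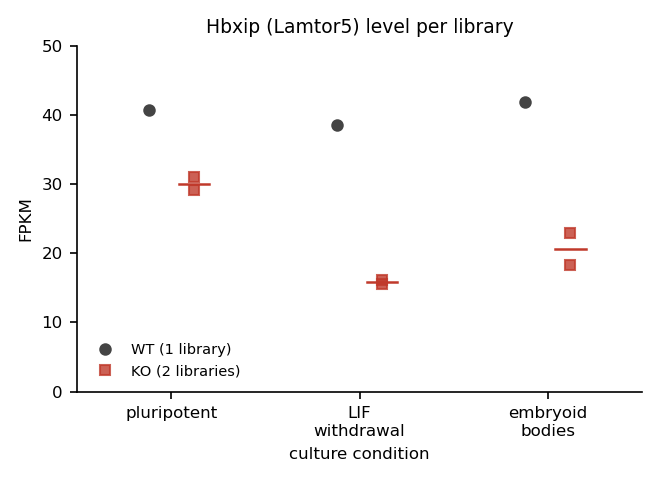
Level of Hbxip in FPKM (vertical axis) in each library of the 3 culture conditions (horizontal axis), with WT as grey circles (1 library per condition) and KO as red squares (2 libraries per condition). Red lines are the KO means, 30.1 FPKM in pluripotent culture, 15.9 FPKM after LIF withdrawal and 20.7 FPKM in embryoid bodies.

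The comparison of KO with WT over the 3 conditions asked which genes differed with Hbxip genotype on average over the cultures. Among the largest rises in KO was Cd99, a cell-surface glycoprotein, with a count ratio of 300.0 (95% counting interval 53.6 to 11871). Magea4, a cancer-testis antigen, had a ratio of 92.7 (31.6 to 451). Cyp2c69, a cytochrome P450, rose by 4.17 ± 0.46, the aldehyde oxidase Aox3 by 4.17 ± 0.62 and the homeobox gene Dmbx1 by 4.03 ± 0.47. The largest falls included Sp5, a zinc-finger factor induced by WNT signalling (-6.12 ± 0.94), Sema6a, a transmembrane semaphorin (-5.68 ± 0.59), and Enpp2, the secreted enzyme autotaxin (-5.59 ± 0.38). Fst, which encodes the activin-binding protein follistatin, had -5.23 ± 1.01, Vrtn -5.22 ± 0.44 and Fndc3c1 -5.01 ± 0.32. Such a change could differ in size between cultures, and the p-values weigh this variation only pooled with the smaller spread within the KO pairs. In pluripotent culture Fst was at 0.58 FPKM in WT and 0.34 and 0.38 FPKM in KO. In embryoid bodies it was at 29.8 FPKM in WT and 0.15 and 0 FPKM in KO. Each of the named genes lay on the same side of WT in both KO libraries of all 3 conditions. Their adjusted p-values ran from 6.07e-05 (Magea4) to 0.00593 (Fst). In all, 1858 genes rose and 1929 fell of 13990 tested, 607 and 907 of them by at least 2-fold. The total of 3787 calls became 5896 without the WT pluripotent library.

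Lysosome and v-ATPase genes rose in KO over the 3 conditions. Of this list 19 rose and 1 fell of 28 tested (22 and 1 adjusted over the list alone), and its median was 0.64 (adjusted p = 7.22e-09, and adjusted p = 0.361 with an estimated correlation). Ctsa, the protective protein cathepsin A, rose by 1.61 ± 0.19, and the v-ATPase subunit genes Atp6v0d1 and Atp6v1b2 by 0.98 ± 0.10 and 0.87 ± 0.08. Genes of the integrated stress response (ATF4 targets) fell. Here 1 rose and 16 fell of 25 tested (1 and 16 adjusted over the list alone), and the median was -0.63 (adjusted p = 1.59e-06, and adjusted p = 0.462 with an estimated correlation). The serine synthesis genes Psat1 (-1.52 ± 0.17) and Phgdh (-0.83 ± 0.07), the mitochondrial folate enzyme gene Mthfd2 (-1.03 ± 0.09) and the stress factor Atf3 (-2.57 ± 0.35) were among those that fell. Among p53 targets 0 rose and 12 fell of 17 tested (1 and 12 adjusted over the list alone), with a median of -0.77 (adjusted p = 3.90e-07, and adjusted p = 0.365 with an estimated correlation). Plk2 had -2.09 ± 0.21, the apoptosis gene Bbc3 -1.37 ± 0.16 and Zmat3 -1.06 ± 0.10. For cholesterol biosynthesis and uptake, 1 rose and 9 fell of 23 tested (1 and 11 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.00447, and adjusted p = 0.462 with an estimated correlation). Dhcr7, which makes cholesterol in the last step of one branch, had -1.27 ± 0.16. Among nucleolar and MYC-driven genes 1 rose and 4 fell of 21 tested (1 and 6 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.0279, and adjusted p = 0.584 with an estimated correlation). The members that fell included Mycn (-2.83 ± 0.26) and Cad, an enzyme of pyrimidine synthesis (-0.92 ± 0.10). This last list was not called without KO pluripotent replicate 2 (median -0.12) or KO LIF withdrawal replicate 2 (median -0.15).

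The naive pluripotency, formative and primed epiblast, and primitive streak lists were also called over the 3 conditions, with the preset correlation only. Of the naive pluripotency genes 6 rose and 2 fell of 17 tested (7 and 2 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.0279, and adjusted p = 0.634 with an estimated correlation), a call lost with limma on quantile-normalized FPKM values. The transcription factors Tfcp2l1 (1.47 ± 0.23) and Nr0b1 (1.41 ± 0.18) rose, as did the AKT coactivator Tcl1 (1.41 ± 0.16), while Dppa3 fell (-3.20 ± 0.47). On the formative and primed epiblast list 1 rose and 8 fell of 11 tested (1 and 8 adjusted over the list alone), with a median of -1.49 (adjusted p = 0.000912, and adjusted p = 0.325 with an estimated correlation). Lef1, a WNT effector, had -3.83 ± 0.40 and Sox3 -2.63 ± 0.20. On the primitive streak and mesendoderm list 1 rose and 10 fell of 12 tested (1 and 10 adjusted over the list alone), with a median of -3.74 (adjusted p = 0.00251, and adjusted p = 0.462 with an estimated correlation). T (brachyury) fell by 5.88 ± 0.84 on the log2 scale and Wnt3, a ligand needed for streak formation, by 5.83 ± 0.48. In pluripotent culture T was at 0.28 FPKM in WT and 0.28 and 0.14 FPKM in KO. Wnt3 was there at 0.18 FPKM in WT and 0 and 0.03 FPKM in KO. Both falls thus came mainly from LIF withdrawal and embryoid bodies. Lefty2, a NODAL antagonist, rose by 1.66 ± 0.13.

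Of the extraembryonic lists, trophoblast genes had 0 higher and 6 lower of 10 tested (0 and 6 adjusted over the list alone), with a median of -1.76 (adjusted p = 0.000161, and adjusted p = 0.325 with an estimated correlation), and Krt7 at -4.00 ± 0.34, Krt19 at -2.12 ± 0.29 and Tfap2c at -1.83 ± 0.22. Extraembryonic endoderm genes had 9 higher and 3 lower of 16 tested (10 and 3 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.00480, and adjusted p = 0.360 with an estimated correlation). The basement-membrane collagens Col4a1 and Col4a2 rose by 1.78 ± 0.21 and 1.86 ± 0.21, while the laminin gene Lamb1 fell (-2.0 ± 0.24). In the 2-cell-like state list 0 rose and 7 fell of 8 tested (0 and 7 adjusted over the list alone), with a median of -2.43 (adjusted p = 1.04e-08, and adjusted p = 0.325 with an estimated correlation). Zscan4f had -2.42 ± 0.24, but reads shared within the Zscan4, Tcstv and Gm8300 families leave single members uncertain. Blood and endothelium genes had 0 higher and 3 lower of 9 tested (1 and 4 adjusted over the list alone), with a median of -1.16 (adjusted p = 0.0334, and adjusted p = 0.408 with an estimated correlation). Gata2 was at -2.25 ± 0.30 and Sox18 at -2.48 ± 0.30. That list's call was lost with limma on log2(FPKM + 1), with or without quantile normalization, and without KO pluripotent replicate 1 (median -1.10). The Y-linked list had 2 higher and 0 lower of 4 tested (3 and 0 adjusted over the list alone), with a median of 0.59 (adjusted p = 0.0273, and adjusted p = 0.348 with an estimated correlation), and it was not called with limma on log2(FPKM + 1), with or without quantile normalization.

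The other 14 lists were not called over the 3 conditions. Ragulator and Rag GTPase genes had 1 higher and 2 lower of 9 tested (3 and 2 adjusted over the list alone) and a median of 0.13 (adjusted p = 0.702), with the Rag GTPase gene Rragc at 0.90 ± 0.14 and Slc38a9, the lysosomal arginine sensor, at -0.95 ± 0.18. General pluripotency genes had 3 higher and 1 lower of 12 tested (3 and 1 adjusted over the list alone) and a median of 0.11 (adjusted p = 0.50), with Lin28a at -0.54 ± 0.12. Neuroectoderm genes had 2 higher and 5 lower of 11 tested (2 and 5 adjusted over the list alone) and a median of -0.40 (adjusted p = 0.0781), with Nes at -2.39 ± 0.21 and Sox11 at -1.49 ± 0.13. Definitive endoderm genes had 1 higher and 3 lower of 10 tested (1 and 4 adjusted over the list alone) and a median of -0.61 (adjusted p = 0.186), with Cldn6 at -3.53 ± 0.40. Autophagy and FLCN-FNIP genes had 6 higher and 2 lower of 20 tested (10 and 3 adjusted over the list alone) and a median of 0.22 (adjusted p = 0.198), with the autophagy receptor Sqstm1 at 0.97 ± 0.21. The ribosomal protein list had 0 higher and 0 lower of 41 tested (0 and 0 adjusted over the list alone) and a median of -0.07 (adjusted p = 0.470). Glycolysis genes had 1 higher and 1 lower of 15 tested (1 and 0 adjusted over the list alone) and a median of -0.13 (adjusted p = 0.594). The hypoxia response list had 1 higher and 2 lower of 17 tested (1 and 2 adjusted over the list alone) and a median of -0.45 (adjusted p = 0.145), with Ddit4, an inhibitor of mTORC1, at -2.60 ± 0.32.

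For 6 of these lists the median, the mean and the test over the 3 conditions did not share a sign, the test being upward in each. Mesoderm and cardiac genes had 3 higher and 2 lower of 14 tested (3 and 2 adjusted over the list alone), a median of -0.03 (adjusted p = 0.470) and a mean of -0.32. Bmp4 rose by 2.79 ± 0.19, while the BMP-responsive Msx1 had -4.37 ± 0.58. Fibroblast and feeder markers had 3 higher and 3 lower of 8 tested (3 and 3 adjusted over the list alone), a median of -0.06 (adjusted p = 0.620) and a mean of -0.34. They held both Vim (1.39 ± 0.10) and Col1a1 (-2.47 ± 0.25). For mTOR pathway components there were 4 higher and 2 lower of 21 tested (4 and 2 adjusted over the list alone), a median of -0.03 (adjusted p = 0.791) and a mean of -0.05. Tsc1 and Tsc2, which together restrain mTORC1, rose by 0.41 ± 0.09 and 0.45 ± 0.07. Cell cycle genes had 2 higher and 1 lower of 20 tested (1 and 1 adjusted over the list alone), a median of 0.06 (adjusted p = 0.583) and a mean of -0.06, with Ccnd1 at -2.73 ± 0.59. NF-kB targets had 1 higher and 1 lower of 12 tested (2 and 3 adjusted over the list alone), a median of 0.05 (adjusted p = 0.700) and a mean of -0.07. Imprinted genes had 7 higher and 8 lower of 20 tested (7 and 8 adjusted over the list alone), a median of -0.06 (adjusted p = 0.952) and a mean of 0.33. Over all 10 comparisons camera called 105 of 270 list tests. It called 0 with an estimated correlation, where the smallest adjusted p was 0.325.

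KO versus WT in pluripotent culture asked what distinguished the genotypes before differentiation. The lysosomal enzyme gene Hexa rose by 3.70 ± 0.13 (adjusted p = 5.71e-09), from 10.3 FPKM in WT to 129 and 117 FPKM in KO. With it rose the lysosomal membrane gene Cd63 (2.82 ± 0.13), Ctsa (2.34 ± 0.09) and the cholesterol transporter gene Npc2 (1.99 ± 0.10). Cyclin D1 (Ccnd1) fell by 4.86 ± 0.15 on the log2 scale (adjusted p = 3.86e-09), and cyclin D2 (Ccnd2) fell to a count ratio of 0.00396 (95% counting interval 0.000477 to 0.0144). H2-Eb1, an MHC class II gene, rose by 6.79 ± 0.32, and Cd99 was at least 24.2-fold higher in KO, its WT library holding no count. Vrtn was at least 16.6-fold lower, and the calcium-binding gene Calb2 fell to a ratio of 0.00907 (0.00109 to 0.0335). In this condition 3574 genes rose and 3674 fell, 1154 and 1628 of them by at least 2-fold. DESeq2 called 4792 genes where edgeR called 7248.

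As a list, lysosome and v-ATPase genes rose in pluripotent culture, where 21 rose and 1 fell of 28 tested (22 and 1 adjusted over the list alone), with a median of 0.88 (adjusted p = 1.79e-13, and adjusted p = 0.325 with an estimated correlation). Integrated stress response genes fell, and here 0 rose and 18 fell of 25 tested (0 and 19 adjusted over the list alone), with a median of -0.68 (adjusted p = 6.03e-09, and adjusted p = 0.325 with an estimated correlation). They included Psat1 (-2.03 ± 0.08), the amino acid transporter gene Slc7a3 (-2.43 ± 0.14) and Chac1, which degrades glutathione (-2.42 ± 0.21). On the hypoxia response list 0 rose and 11 fell of 17 tested (1 and 13 adjusted over the list alone), with a median of -1.04 (adjusted p = 0.00455, and adjusted p = 0.678 with an estimated correlation). Ddit4 had -3.26 ± 0.35 and the collagen hydroxylase gene P4ha2 -1.75 ± 0.28. On the glycolysis list 1 rose and 9 fell of 15 tested (1 and 9 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0317, and adjusted p = 0.675 with an estimated correlation), and Pgk1 had -1.23 ± 0.16 and Ldha -0.93 ± 0.14. Extraembryonic endoderm genes had 11 higher and 3 lower of 16 tested (11 and 3 adjusted over the list alone), with a median of 1.07 (adjusted p = 0.000499, and adjusted p = 0.497 with an estimated correlation). Among them Apoe rose by 3.65 ± 0.15 and Amn, a receptor subunit of the visceral endoderm, by 3.60 ± 0.28. Formative genes had 1 higher and 6 lower of 11 tested (1 and 6 adjusted over the list alone), with a median of -1.13 (adjusted p = 0.000321, and adjusted p = 0.406 with an estimated correlation), and neuroectoderm genes 2 higher and 8 lower of 11 tested (2 and 8 adjusted over the list alone), with a median of -0.83 (adjusted p = 0.0149, and adjusted p = 0.366 with an estimated correlation). The glycolysis, formative and neuroectoderm lists were not called with limma on log2(FPKM + 1). Zic2 had -4.22 ± 0.24, the de novo DNA methyltransferase Dnmt3a -1.98 ± 0.11, and the neural genes En2 -2.54 ± 0.29 and Tubb3 -1.10 ± 0.11. Bmp4 rose by 3.22 ± 0.17 and Hand1, a mesoderm and trophoblast factor, by 4.12 ± 0.39. Among pluripotency genes Klf2 (0.75 ± 0.10) and Tcl1 (0.91 ± 0.09) rose, and Fgf4 (-0.83 ± 0.10), Lin28a (-0.89 ± 0.09) and Sox2 (-0.54 ± 0.09) fell.

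Ribosomal protein genes were higher in KO pluripotent cells, where 31 rose and 0 fell of 41 tested (32 and 0 adjusted over the list alone), with a median of 0.41 (adjusted p = 3.25e-06, and adjusted p = 0.441 with an estimated correlation), and with limma on log2(FPKM + 1) the median was 0.28 and called, but after quantile normalization of these values it was 0.00 and not called. Rps15 rose by 0.80 ± 0.09, Rps19 by 0.75 ± 0.09 and Rps20 by 0.74 ± 0.08. Fold changes in this comparison also ran with gene length. Their median was 0.27 in the shortest quintile of genes (median length 997 bases) and -0.25 in the longest (median length 5812 bases). After a correction for length and GC content the ribosomal median was 0.20 (adjusted p = 0.0359). The Ragulator genes Lamtor1 and Lamtor4 rose by 0.78 ± 0.10 and 1.15 ± 0.15. Of the Rag GTPase genes, Rragc had 1.36 ± 0.13 and Rragb -1.18 ± 0.12.

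**Figure D2:**
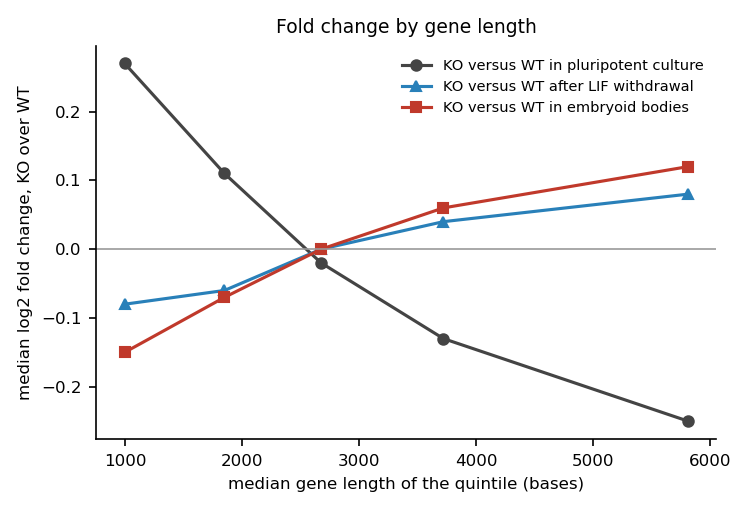
Median log2 fold change, KO over WT, of all tested genes (vertical axis) in 5 quintiles of gene length, drawn at each quintile's median length in bases (horizontal axis). In pluripotent culture (grey circles) it ran from 0.27 to -0.25, after LIF withdrawal (blue triangles) from -0.08 to 0.08, and in embryoid bodies (red squares) from -0.15 to 0.12.

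KO versus WT after LIF withdrawal asked how the genotypes differed once cells had been without LIF for 96 h. T fell by 6.49 ± 0.30 on the log2 scale (adjusted p = 3.74e-08), from 17.5 FPKM in WT to 0.18 and 0.18 FPKM in KO. T held only 8 counts in KO, against 380 in WT. The streak genes Wnt8a (-4.59 ± 0.30) and Wnt3 (-6.07 ± 0.47), Vrtn (-6.25 ± 0.31) and the tight-junction gene Cldn6 (-5.0 ± 0.12) fell with T. Sp5 fell to a count ratio of 0.00407 (95% counting interval 0.000102 to 0.0231). The naive pluripotency factors Tfcp2l1 (2.18 ± 0.11), Esrrb (1.41 ± 0.10) and Tbx3 (1.21 ± 0.09) rose in KO, as did Tcl1 (1.74 ± 0.10). Calls numbered 2569 rises and 2442 falls, 713 and 1089 of them at least 2-fold. Against 5011 genes with edgeR, DESeq2 called 2840.

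The naive list had 9 higher and 4 lower of 17 tested (10 and 4 adjusted over the list alone) after LIF withdrawal, with a median of 0.41 (adjusted p = 4.23e-07, and adjusted p = 0.462 with an estimated correlation). The primitive streak list had 1 higher and 9 lower of 12 tested (1 and 10 adjusted over the list alone), with a median of -3.68, or -3.75 with its low-count genes at their bounds (adjusted p = 5.46e-08, and adjusted p = 0.325 with an estimated correlation). Formative genes had 1 higher and 7 lower of 11 tested (1 and 8 adjusted over the list alone), with a median of -1.35 (adjusted p = 1.07e-06, and adjusted p = 0.325 with an estimated correlation), the de novo methyltransferase Dnmt3b at -1.75 ± 0.11 and Pou3f1 at -2.25 ± 0.19. Trophoblast genes had 0 higher and 8 lower of 10 tested (2 and 8 adjusted over the list alone), with a median of -2.08 (adjusted p = 7.58e-08, and adjusted p = 0.325 with an estimated correlation). The keratins Krt7 (-4.66 ± 0.47), Krt19 (-3.03 ± 0.25), Krt18 (-2.59 ± 0.15) and Krt8 (-2.17 ± 0.14) fell. Lysosome genes had 21 higher and 1 lower of 28 tested (21 and 3 adjusted over the list alone), with a median of 0.47 (adjusted p = 2.72e-05, and adjusted p = 0.419 with an estimated correlation), Ctsa at 1.26 ± 0.09 and Hexa at 1.09 ± 0.11. Stress response genes had 1 higher and 18 lower of 25 tested (2 and 19 adjusted over the list alone), with a median of -0.85 (adjusted p = 9.97e-07, and adjusted p = 0.325 with an estimated correlation) and Chac1 at -2.44 ± 0.24. Cholesterol genes had 0 higher and 15 lower of 23 tested (1 and 18 adjusted over the list alone), with a median of -0.46 (adjusted p = 1.40e-05, and adjusted p = 0.406 with an estimated correlation), Dhcr7 at -1.35 ± 0.12 and Idi1 at -0.91 ± 0.09. The p53 target list had 1 higher and 12 lower of 17 tested (1 and 12 adjusted over the list alone), with a median of -0.94 (adjusted p = 3.90e-10, and adjusted p = 0.442 with an estimated correlation), Perp at -3.53 ± 0.20 and Btg2 at -2.88 ± 0.18. Ribosomal protein genes had 1 higher and 28 lower of 41 tested (1 and 32 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.000111, and adjusted p = 0.462 with an estimated correlation), and they were not called after quantile normalization. Median fold changes by length ran from -0.08 to 0.08 here, and the corrected ribosomal median was -0.21 (adjusted p = 0.00390). Mycn fell (-3.81 ± 0.11) and Myc rose (1.23 ± 0.13). The neural factor Sox1 rose (4.64 ± 0.34) while Nes, an intermediate filament of neural progenitors, fell (-3.01 ± 0.15).

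KO versus WT in embryoid bodies asked the same of cells differentiating as aggregates. Fst fell by 8.65 ± 0.33 on the log2 scale (adjusted p = 8.66e-09), T by 7.62 ± 0.31, Sema6a by 7.29 ± 0.19 and Enpp2 by 6.09 ± 0.29. KO embryoid bodies held only 4 counts of Fst and 5 of T, against 843 and 509 in WT, so the counting error of these 2 falls is larger than the values after ±. Fgf8 (-5.77 ± 0.32) and Wnt8a (-4.37 ± 0.27) of the streak list fell too. Foxa2, a factor of definitive endoderm, fell to a count ratio of 0.00537 (95% counting interval 0.000134 to 0.0307). Esrrb (1.71 ± 0.10), Tcl1 (1.67 ± 0.10), Tfcp2l1 (1.61 ± 0.11) and Tbx3 (1.41 ± 0.10) rose. Cd99 was at least 54.7-fold and Magea4 at least 22.6-fold higher in KO. The counts were 2720 rises and 2484 falls, 860 and 822 of at least 2-fold. DESeq2 called 2889 where edgeR called 5204.

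Naive pluripotency genes rose as a list in KO embryoid bodies, where 14 rose and 2 fell of 17 tested (14 and 2 adjusted over the list alone), with a median of 1.06 (adjusted p = 3.11e-13, and adjusted p = 0.382 with an estimated correlation). Primitive streak genes had 1 higher and 10 lower of 12 tested (1 and 10 adjusted over the list alone), with a median of -5.05, or -4.66 with its low-count genes at their bounds (adjusted p = 9.36e-13, and adjusted p = 0.325 with an estimated correlation). The formative list had 3 higher and 7 lower of 11 tested (3 and 8 adjusted over the list alone), with a median of -1.67 (adjusted p = 2.95e-09, and adjusted p = 0.325 with an estimated correlation). Its members Fgf5 (-3.08 ± 0.15), Dnmt3b (-2.28 ± 0.11) and Pou3f1 (-2.62 ± 0.17) fell. Among trophoblast genes 1 rose and 7 fell of 10 tested (1 and 8 adjusted over the list alone), with a median of -1.41 (adjusted p = 0.000206, and adjusted p = 0.325 with an estimated correlation). Among lysosome genes 21 rose and 1 fell of 28 tested (21 and 1 adjusted over the list alone), with a median of 0.70 (adjusted p = 6.32e-11, and adjusted p = 0.325 with an estimated correlation), and Ctsa had 1.32 ± 0.09 and Hexa 1.22 ± 0.11. Among ribosomal protein genes 0 rose and 28 fell of 41 tested (0 and 32 adjusted over the list alone), with a median of -0.32 (adjusted p = 1.01e-06, and adjusted p = 0.419 with an estimated correlation), not called after quantile normalization. The length trend ran from -0.15 to 0.12, and the corrected ribosomal median was -0.22 (adjusted p = 0.00121). Hnf4a, an endoderm factor, rose by 4.18 ± 0.25, Sox1 by 3.86 ± 0.45, Ncam1 by 1.88 ± 0.18 and Pecam1 by 1.90 ± 0.11. From WT pluripotent culture to WT embryoid bodies, Ncam1 went from 7.13 to 2.03 FPKM and Pecam1 from 32.1 to 10.25 FPKM. KO embryoid bodies held 7.92 and 6.81 FPKM of Ncam1 and 40.2 and 35.9 FPKM of Pecam1. The growth factor gene Igf2 fell (-3.75 ± 0.28), as did Mycn (-2.33 ± 0.10) and Cldn6 (-3.19 ± 0.10).

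**Figure D3:**
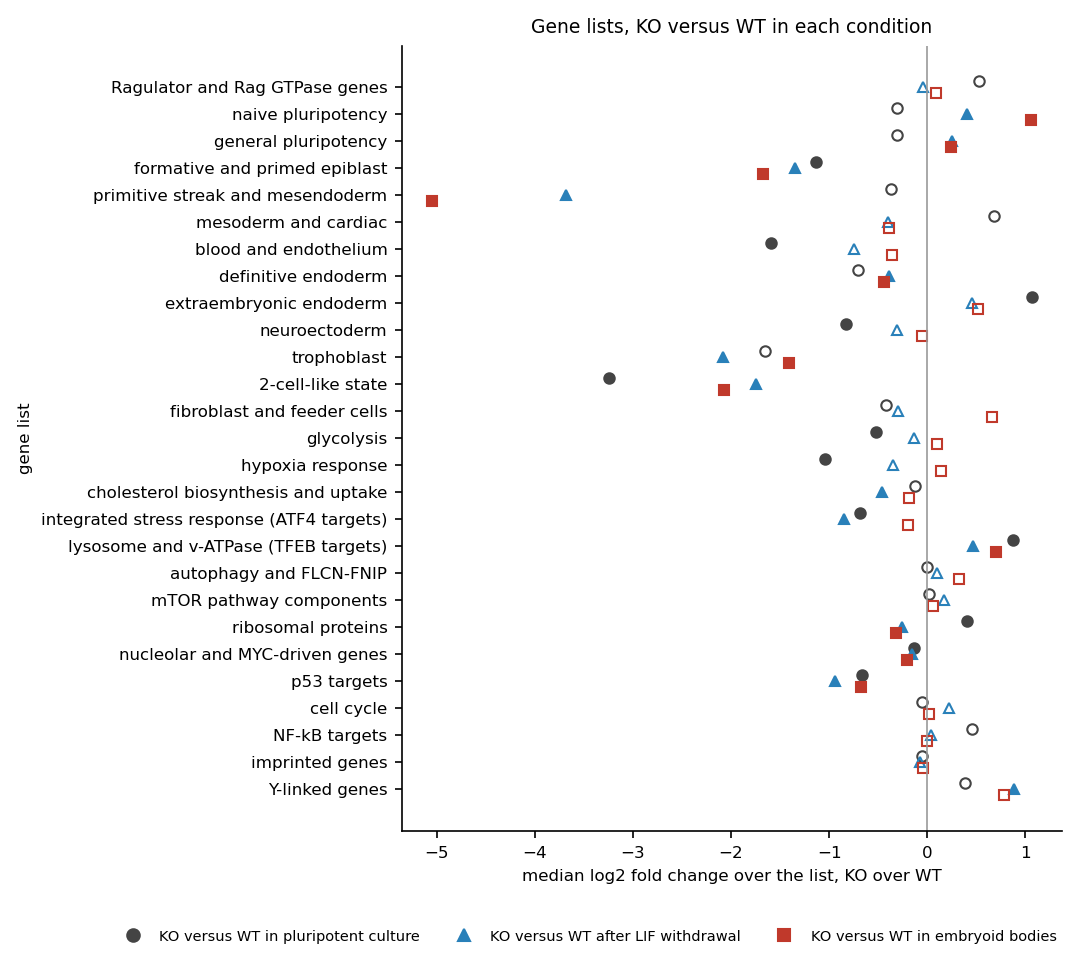
Median log2 fold change, KO over WT (horizontal axis), of the tested members of each gene list (vertical axis) in pluripotent culture (grey circles), after LIF withdrawal (blue triangles) and in embryoid bodies (red squares), filled where camera's adjusted p passed the threshold with a preset correlation. Lysosome genes lay at 0.88, 0.47 and 0.70 in these conditions and primitive streak genes at -0.37, -3.68 and -5.05.

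LIF withdrawal versus pluripotent culture in WT asked what the unmodified cells did when LIF was removed. Fgf8 rose at least 44.1-fold from no count. T rose by 5.98 ± 0.36, the formative gene Fgf5 by 5.62 ± 0.33, Wnt8a by 5.13 ± 0.41 and Enpp2 by a count ratio of 51.9 (95% counting interval 17.4 to 254). The naive genes Klf4 (-2.85 ± 0.14), Tfcp2l1 (-2.21 ± 0.12), Tcl1 (-1.71 ± 0.11) and Zfp42 (-1.46 ± 0.10) fell, as did Emp1, a membrane protein gene (-4.73 ± 0.36). Of the naive list 0 rose and 13 fell of 17 tested (0 and 13 adjusted over the list alone), with a median of -0.98 (adjusted p = 1.18e-21, and adjusted p = 0.325 with an estimated correlation). Of the streak list 9 rose and 0 fell of 12 tested (9 and 0 adjusted over the list alone), with a median of 2.53 (adjusted p = 9.28e-13, and adjusted p = 0.325 with an estimated correlation). Of the formative list 10 rose and 1 fell of 11 tested (10 and 1 adjusted over the list alone), with a median of 1.66 (adjusted p = 1.79e-13, and adjusted p = 0.325 with an estimated correlation), and Pou3f1 had 2.62 ± 0.24. Of the imprinted genes 10 rose and 0 fell of 20 tested (12 and 1 adjusted over the list alone), with a median of 0.70 (adjusted p = 1.38e-05, and adjusted p = 0.325 with an estimated correlation), and H19 had 3.65 ± 0.61 and Peg3 2.45 ± 0.15. In this comparison of 1 library with 1, 1622 genes rose and 1245 fell. DESeq2 called 1228 genes against 2867 with edgeR.

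LIF withdrawal versus pluripotent culture in KO put the same question to KO cells, with 2 libraries on each side. Dnmt3a rose by 2.94 ± 0.10, Zic2 by 3.90 ± 0.22, Otx2, a factor of the formative epiblast, by 2.67 ± 0.18, and the ectonucleotidase gene Enpp3 by 4.65 ± 0.17. Mesothelin (Msln) fell by 6.84 ± 0.26 on the log2 scale and the calcium-binding gene S100a6 by 6.5 ± 0.20. Formative genes had 8 higher and 0 lower of 11 tested (8 and 0 adjusted over the list alone), with a median of 2.68 (adjusted p = 3.26e-07, and adjusted p = 0.325 with an estimated correlation). The streak list was not called, with 3 higher and 1 lower of 12 tested (3 and 1 adjusted over the list alone) and a median of 0.33, or 0.15 with its low-count genes at their bounds (adjusted p = 0.401). Its member Eomes rose by 2.11 ± 0.14, while T was at 0.28 and 0.14 FPKM in pluripotent culture and 0.18 and 0.18 FPKM after LIF withdrawal. Naive genes had 3 higher and 9 lower of 17 tested (3 and 9 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0153, and adjusted p = 0.658 with an estimated correlation), Klf2 at -1.23 ± 0.08 and Tcl1 at -0.88 ± 0.07. That call was lost with limma on log2(FPKM + 1), with or without quantile normalization, and without KO LIF withdrawal replicate 2 (median -0.22). Of the lysosome genes 5 rose and 15 fell of 28 tested (5 and 15 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.00788, and adjusted p = 0.515 with an estimated correlation), Cd63 at -1.45 ± 0.09 and Hexa at -1.02 ± 0.08. Of the ribosomal protein genes 1 rose and 38 fell of 41 tested (1 and 38 adjusted over the list alone), with a median of -0.56 (adjusted p = 1.51e-11, and adjusted p = 0.348 with an estimated correlation), and neither of these lists was called after quantile normalization. Fold changes by length ran from -0.48 in the shortest quintile to 0.48 in the longest, and the corrected ribosomal median was -0.13 (adjusted p = 0.0380). In all, 4227 genes rose and 4052 fell.

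The difference between KO and WT in the response to LIF withdrawal tested whether the responses themselves differed. Naive factors had higher responses in KO, with differences of 2.24 ± 0.16 for Klf4, 1.60 ± 0.12 for Klf5, 1.43 ± 0.14 for Tfcp2l1 and 1.34 ± 0.12 for Tbx3. Among streak and formative genes the difference was -6.25 ± 0.87 for T, -5.33 ± 0.68 for Wnt8a, -1.64 ± 0.17 for Dnmt3b, -2.24 ± 0.32 for Pou3f1 and 2.20 ± 0.16 for Dnmt3a. Dnmt3a started at 29.5 FPKM in WT and 6.07 and 7.38 FPKM in KO. Without LIF it was at 48.35 FPKM in WT and 51.0 and 56.5 FPKM in KO. Fgf8 went from 0 to 10.7 FPKM in WT. In KO it was at 0.17 and 0.50 FPKM in pluripotent culture and at 0.63 and 0.33 FPKM without LIF. Hexa (-2.61 ± 0.17), Cd63 (-2.47 ± 0.17), Krt8 (-3.68 ± 0.20) and the matrix enzyme gene Loxl4 (-7.56 ± 0.52) had lower responses in KO. Ccnd1 (2.77 ± 0.21) and Stra8, a meiotic gene (4.79 ± 0.46), had higher ones. Ccnd1 started at 51.7 FPKM in WT and 1.28 and 1.98 FPKM in KO. Without LIF it was still lower in KO, at 12.6 and 15.6 FPKM against 62.7 FPKM in WT. The naive list had 10 higher and 1 lower of 17 tested (11 and 2 adjusted over the list alone) and a median difference of 0.73 (adjusted p = 1.94e-06, and adjusted p = 0.462 with an estimated correlation). The streak list had 1 higher and 6 lower of 12 tested (1 and 6 adjusted over the list alone) and a median difference of -2.66, or -0.23 without its low-count genes (adjusted p = 0.0344, and adjusted p = 0.451 with an estimated correlation). Leaving out low-count genes drops those nearly silent in a group, and with groups of under 3 counts set at 3 the median difference was -3.36. The streak call was lost with the length and GC correction (median -2.66, adjusted p = 0.0587), without KO pluripotent replicate 2 (median -1.46) and without KO LIF withdrawal replicate 1 (median -2.74). It was also lost with the replicate number as a block. Lysosome genes had 1 higher and 14 lower of 28 tested (2 and 16 adjusted over the list alone) and a median difference of -0.47 (adjusted p = 2.35e-06, and adjusted p = 0.406 with an estimated correlation). For ribosomal proteins there were 0 higher and 36 lower of 41 tested (0 and 39 adjusted over the list alone), with a median difference of -0.70 (adjusted p = 2.19e-18, and adjusted p = 0.325 with an estimated correlation), not called after quantile normalization. The length trend ran from -0.33 to 0.34 and the corrected ribosomal median was -0.42 (adjusted p = 5.37e-09). Responses of 4528 genes differed, 2446 higher and 2082 lower in KO, while DESeq2 called 2374.

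Embryoid bodies versus pluripotent culture in WT asked which genes the unmodified cells changed in aggregates. Fgf8 rose at least 124-fold, Fgf5 by 7.47 ± 0.30, T by 6.43 ± 0.35, Fst by 5.67 ± 0.32 and Wnt8a by 5.64 ± 0.40. Foxa2 rose by a count ratio of 95.5 (95% counting interval 16.7 to 3814), and Inhbb, an activin subunit gene, fell to a ratio of 0.00207 (0.000250 to 0.00749). Klf4 (-3.14 ± 0.14), Tfcp2l1 (-2.26 ± 0.12), Tbx3 (-1.98 ± 0.11) and Esrrb (-1.51 ± 0.11) fell. Streak genes had 10 higher and 0 lower of 12 tested (10 and 0 adjusted over the list alone), with a median of 3.4 (adjusted p = 2.51e-10, and adjusted p = 0.325 with an estimated correlation). Formative genes had 8 higher and 1 lower of 11 tested (8 and 1 adjusted over the list alone), with a median of 2.15 (adjusted p = 1.25e-09, and adjusted p = 0.325 with an estimated correlation). Naive genes had 2 higher and 14 lower of 17 tested (2 and 14 adjusted over the list alone), with a median of -1.17 (adjusted p = 1.79e-13, and adjusted p = 0.371 with an estimated correlation). Stress response genes had 0 higher and 20 lower of 25 tested (0 and 21 adjusted over the list alone), with a median of -0.94 (adjusted p = 4.50e-12, and adjusted p = 0.325 with an estimated correlation), Psat1 at -1.38 ± 0.10 and Asns, asparagine synthetase, at -1.2 ± 0.09. Ribosomal protein genes had 35 higher and 0 lower of 41 tested (37 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 6.66e-11, and adjusted p = 0.348 with an estimated correlation), not called after quantile normalization. A total of 2760 genes rose and 2640 fell. DESeq2 called 2929 genes and edgeR 5400.

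Embryoid bodies versus pluripotent culture in KO asked this of KO cells, again with 2 libraries on each side. Zic2 rose by 4.76 ± 0.21, Car14 by 3.92 ± 0.25, Otx2 by 3.56 ± 0.18 and Dnmt3a by 2.34 ± 0.10, and Vrtn rose at least 28.0-fold. Tesc, a calcium-binding regulator, fell by 5.74 ± 0.25 on the log2 scale, and Msln fell to a count ratio of 0.00313 (95% counting interval 0.000644 to 0.00917). The formative list had 10 higher and 0 lower of 11 tested (10 and 0 adjusted over the list alone), with a median of 2.45 (adjusted p = 7.22e-09, and adjusted p = 0.325 with an estimated correlation). The streak list was not called, with 2 higher and 2 lower of 12 tested (2 and 2 adjusted over the list alone), a median of 0.22 (adjusted p = 0.502), a mean of -0.17 and an upward test. Eomes rose by 2.31 ± 0.14, while T was at 0.05 and 0.18 FPKM in KO embryoid bodies against 24.0 FPKM in WT ones. The naive list was not called either, with 6 higher and 8 lower of 17 tested (6 and 9 adjusted over the list alone) and a median of -0.18 (adjusted p = 0.378). It held Tfcp2l1 (-1.40 ± 0.08), Klf4 (-1.02 ± 0.09), Fgf4 (0.97 ± 0.08) and Nr0b1 (0.88 ± 0.10). Ribosomal protein genes had 1 higher and 28 lower of 41 tested (1 and 28 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.00463, and adjusted p = 0.523 with an estimated correlation), but the median was 0.02 after the length and GC correction and 0.00 after quantile normalization, and neither was called. Of all tested genes, 4342 rose and 4193 fell.

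The difference between KO and WT in the response to embryoid body culture tested whether these responses differed. T (-7.38 ± 0.92), Fst (-8.06 ± 0.78), Wnt8a (-5.11 ± 0.66) and Mixl1, another streak gene (-4.31 ± 0.63), had lower responses in KO. Naive factors had higher ones, with 2.12 ± 0.17 for Klf4, 1.73 ± 0.14 for Fgf4, 1.54 ± 0.13 for Tbx3 and 1.48 ± 0.12 for Klf5. Of the formative genes, Dnmt3a (2.72 ± 0.16) and Zic2 (3.29 ± 0.31) had higher responses in KO, and Dnmt3b (-2.17 ± 0.17) and Pou3f1 (-2.60 ± 0.31) had lower ones. Zic2 went from 37.5 to 101.9 FPKM in WT and from 1.2 and 2.5 to 53.9 and 53.7 FPKM in KO, still below WT. Dnmt3a went from 29.5 to 22.3 FPKM in WT and from 6.07 and 7.38 to 34.8 and 40.0 FPKM in KO. Ccnd1 (3.98 ± 0.22), the endothelial receptor gene Tek (4.51 ± 0.29) and the aspartic protease gene Napsa (5.56 ± 0.32) had higher responses. In WT Ccnd1 went from 51.7 to 18.1 FPKM, and in KO from 1.28 and 1.98 to 10.2 and 9.51 FPKM, still below WT. Tek went from 4.89 to 2.0 FPKM in WT and from 0.44 and 0.50 to 5.16 and 4.23 FPKM in KO. For Ccnd1, Tek, Dnmt3a and Zic2 the difference thus includes a lower start in KO pluripotent cells. Apoe (-2.99 ± 0.18), Krt8 (-3.41 ± 0.21) and Hexa (-2.48 ± 0.17) had lower ones. Naive pluripotency genes had 12 higher and 0 lower of 17 tested (13 and 1 adjusted over the list alone) and a median difference of 1.04 (adjusted p = 3.41e-09, and adjusted p = 0.441 with an estimated correlation). Streak genes had 1 higher and 6 lower of 12 tested (1 and 7 adjusted over the list alone) and a median difference of -4.12, or -0.49 without its low-count genes (adjusted p = 0.0156, and adjusted p = 0.419 with an estimated correlation), a call lost without KO pluripotent replicate 2 (median -4.13). Stress response genes had 15 higher and 1 lower of 25 tested (16 and 1 adjusted over the list alone) and a median difference of 0.62 (adjusted p = 0.000246, and adjusted p = 0.325 with an estimated correlation). Hypoxia response genes had 11 higher and 0 lower of 17 tested (11 and 0 adjusted over the list alone) and a median difference of 1.27 (adjusted p = 0.00463, and adjusted p = 0.678 with an estimated correlation), with Bnip3 at 2.73 ± 0.53. Ribosomal protein genes had 0 higher and 37 lower of 41 tested (0 and 39 adjusted over the list alone) and a median difference of -0.75 (adjusted p = 6.29e-17, and adjusted p = 0.325 with an estimated correlation), not called after quantile normalization. The length trend ran from -0.43 to 0.39, and the corrected ribosomal median was -0.45 (adjusted p = 1.87e-07). Responses of 5857 genes differed, 3127 higher and 2730 lower in KO, and DESeq2 called 3284.

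**Figure D4:**
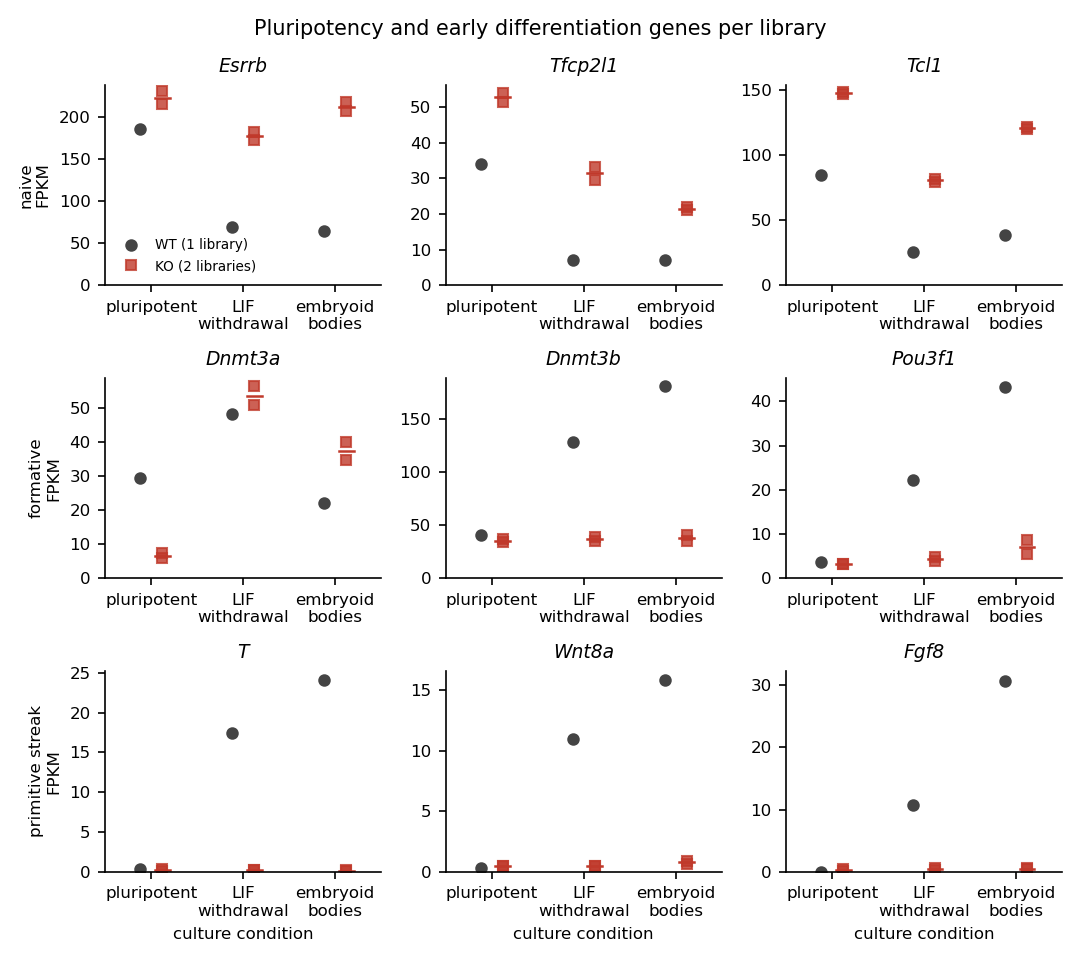
Levels in FPKM (vertical axes, each from 0) of naive (Esrrb, Tfcp2l1, Tcl1), formative (Dnmt3a, Dnmt3b, Pou3f1) and primitive streak genes (T, Wnt8a, Fgf8) in each library of the 3 culture conditions (horizontal axes), with WT as grey circles (1 library), KO as red squares (2 libraries) and KO means as lines. T reached 17.5 FPKM after LIF withdrawal and 24.0 FPKM in embryoid bodies in WT, against 0.18 and 0.18 FPKM and 0.05 and 0.18 FPKM in the KO libraries.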

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

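The tests of length, GC content, the response of KO cells and imprinted genes were chosen only after the results were seen, while the count of other splits was planned. The gene and list values given first are differences between KO and WT in the response to a change of culture, by edgeR's test of the difference itself or, for lists, by camera. No list call in this section passed with an estimated correlation. Responses of 4528 genes differed for LIF withdrawal and of 5857 genes for embryoid bodies. A difference in response also holds any difference already present in pluripotent culture. There the hypoxia, glycolysis, stress response, neuroectoderm and formative lists were lower in KO, and the lysosome and ribosomal protein lists were higher. Of single genes, Ccnd1, Tek, Dnmt3a, Zic2 and Zscan4b of the 2-cell-like list were lower in KO there. With LIF withdrawal Zscan4b went from 25.9 to 27.6 FPKM in WT and from 0.93 and 1.8 to 7.38 and 7.64 FPKM in KO. A higher response in KO is therefore not always a higher level after the change of culture.

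For LIF withdrawal the median difference of the naive list was 0.73, of general pluripotency 0.63, of neuroectoderm 0.76, of the 2-cell-like state 1.17, of hypoxia response 0.71 and of cell cycle genes 0.24. It was below 0 for primitive streak (-2.66, and -0.23 without its low-count genes), trophoblast (-1.43), ribosomal protein (-0.70), lysosome (-0.47), p53 target (-0.40) and extraembryonic endoderm genes (-0.30). With groups of under 3 counts set at 3 the streak median was -3.36. Only the naive, general pluripotency, neuroectoderm, lysosome and ribosomal calls for LIF withdrawal held with each KO library left out. The WT libraries could not be left out here, each being alone in its group. Of these calls, that of neuroectoderm was lost with limma on log2(FPKM + 1) (median 0.52). That of ribosomal protein genes was kept there but lost once these values were quantile-normalized (median -0.16). Without KO pluripotent replicate 1 the calls of 2-cell-like, hypoxia, p53 and extraembryonic endoderm genes were lost (medians 0.79, 0.39, -0.38 and -0.20). Without KO pluripotent replicate 2 those of streak, trophoblast and cell cycle genes were lost (medians -1.46, -1.10 and 0.20). The streak call was also lost with the length and GC correction, with the median still at -2.66 (SD 3.64 before and 3.58 after) but an adjusted p of 0.0587 in place of 0.0344. The 2-cell-like, hypoxia, p53 and extraembryonic endoderm calls were lost with limma on log2(FPKM + 1) too. With the replicate number as a block the streak, 2-cell-like and extraembryonic endoderm calls for LIF withdrawal were lost. For embryoid bodies the median difference was 1.04 for naive, 0.57 for general pluripotency, 0.77 for neuroectoderm, 0.64 for glycolysis, 1.27 for hypoxia response and 0.62 for stress response genes. It was -4.12 for primitive streak (-0.49 without its low-count genes), -0.75 for ribosomal protein and -0.40 for lysosome genes. By gene length, the median difference of all tested genes for embryoid bodies ran from -0.43 in the shortest quintile to 0.39 in the longest. The streak call for embryoid bodies was lost without KO pluripotent replicate 2 (median -4.13). For embryoid bodies the ribosomal call was lost with limma on quantile-normalized FPKM values (median -0.11). The neuroectoderm and lysosome calls were lost with limma on log2(FPKM + 1) (medians 0.64 and -0.26). The neuroectoderm call was also lost without KO pluripotent replicate 1 (median 0.61) or 2 (median 1.2), and the lysosome call without KO pluripotent replicate 1 (median -0.36) or KO embryoid body replicate 2 (median -0.34). With the replicate number as a block the neuroectoderm call for embryoid bodies was lost too.

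Among single genes, responses to LIF withdrawal were higher in KO for Stra8 (4.79), Ccnd1 (2.77), Klf4 (2.24), Dnmt3a (2.20), Klf5 (1.60), Tfcp2l1 (1.43) and Tbx3 (1.34). They were lower for Loxl4 (-7.56), T (-6.25), Wnt8a (-5.33), Krt8 (-3.68), Hexa (-2.61), Cd63 (-2.47), Pou3f1 (-2.24), Dnmt3b (-1.64) and Hbxip (-0.91). Responses to embryoid body culture were higher in KO for Napsa (5.56), Tek (4.51), Ccnd1 (3.98), Zic2 (3.29), Bnip3 (2.73), Dnmt3a (2.72), Klf4 (2.12), Fgf4 (1.73), Tbx3 (1.54) and Klf5 (1.48). They were lower for Fst (-8.06), T (-7.38), Wnt8a (-5.11), Mixl1 (-4.31), Krt8 (-3.41), Apoe (-2.99), Pou3f1 (-2.60), Hexa (-2.48), Dnmt3b (-2.17) and Hbxip (-0.71).

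Primitive streak and mesendoderm genes had a lower response in KO than in WT in embryoid bodies. The fitted trends with gene length and GC content gave the members of this list differences of only -0.46 to 0.11, and less these the median was -4.18 (SD 2.84) with groups of under 3 counts set at 3, which argues against the trends as the whole cause. Over the 7 members with more than 3 counts in every group the corrected median was -0.59 (SD 3.25), a set that leaves out genes nearly silent in any of the groups. KO cells as a whole did not stay as they were in pluripotent culture, since the formative and primed epiblast list rose in them with a median of 2.45. That list started lower in KO than in WT and was still lower in embryoid bodies, so its rise does not show a full formative response. A loss or delay of streak formation in the KO cells may account for the pattern and stays open, as does a difference between these particular lines, since every WT value rests on 1 library per condition.

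Ribosomal protein genes were higher in KO in pluripotent culture, by a median of 0.41, a call that did not pass with an estimated correlation (adjusted p = 0.441). With the trends with gene length and GC content removed the median was 0.20, more than 2 standard errors above 0. That error comes from the spread over the member genes, takes them as independent and does not measure the spread between libraries. These trends could therefore be part of the pattern, and the test cannot say whether they are all of it. With limma on log2(FPKM + 1) the median was 0.28 and called, and quantile normalization of the same values took it to 0.00. A shift shared by highly expressed genes, from the cells or from the libraries, therefore stays open.

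Genes called between KO and WT over the 3 conditions numbered 3787. Of the 81 estimable splits of the 9 libraries, only the real one, 1 in all, gave as many genes, and the highest other split called 1. Every other split mixes WT with KO libraries, so a lasting difference between the lines adds to its spread and keeps its calls low. Libraries that are repeated samples of the same lines are also not free to be swapped. The count of splits therefore cannot exclude a chance difference between the lines or cultures sampled. A difference between the cell lines unrelated to Hbxip cannot be told apart from the genotype, because all WT libraries carry one genotype label and all KO libraries the other, and the labels do not say how the lines were derived. Of 20 tested imprinted genes, whose expression is known to vary between embryonic stem cell lines, 15 differed between KO and WT, which such a difference would give and a genotype effect could give too.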

How the results depend on the processing

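DESeq2, limma on log2(FPKM + 1) as an alternative, the length and GC corrections and the fits without the pluripotent libraries were chosen after seeing the data. Where a count of called genes moved by over 1.5 times, the cause was not tested. DESeq2 called 4792 genes for KO versus WT in pluripotent culture, 2840 after LIF withdrawal and 2889 in embryoid bodies. It called 1228 for LIF withdrawal and 2929 for embryoid bodies in WT, and 2374 and 3284 for the differences between responses. Limma with the replicate block as a random effect called 7231 genes over the 3 conditions, with an estimated correlation within blocks of -0.291. Its blocks were the WT libraries, KO number 1 and KO number 2, so genotype lay between blocks. A negative correlation within such blocks lowers the error of the genotype difference, so this count is no sign of firmer calls. No list was called with an estimated correlation (0 of 270, against 105), and the cause was not tested. Camera called 77 lists on log2(FPKM + 1), 74 after quantile normalization of these values, 103 with median-ratio scaling of the counts and 110 with the length and GC correction. Ribosomal protein genes in KO embryoid bodies against pluripotent culture reversed, to 0.02 with the length and GC correction and 0.00 with limma on quantile-normalized FPKM values, against -0.16 with limma on log2(FPKM + 1) as it stands. So did the uncalled change of Hbxip with LIF withdrawal in WT, to 0.065 with the length and GC correction and 0.05 with length alone. The cause was not tested in either case.

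With 1 library left out, calls ranged from 2544 to 5896 over the 3 conditions, 5984 to 7440 in pluripotent culture, 4274 to 4928 after LIF withdrawal and 3812 to 5440 in embryoid bodies. They ranged from 2428 to 3044 for LIF withdrawal in WT, 6917 to 8018 in KO and 3650 to 4596 for the difference, and from 4948 to 5657, 6860 to 8691 and 4606 to 6045 for embryoid bodies. List calls ranged from 92 to 104, with only KO libraries left out. WT libraries were left out only for the genes over the 3 conditions. The other ranges therefore do not show how far the calls rest on the 1 WT library of a condition. The highest count over the 3 conditions came without the WT pluripotent library, and a lone library left in a group was assumed to vary like the others. Without all pluripotent libraries 5468 genes were called over the other conditions, 3371 of them among the 3787, and 4928 after LIF withdrawal and 5115 in embryoid bodies. The labels do not say what the KO numbers stand for, and the main fits did not take them as pairs. The correlations below leave open that a number stands for 1 culture or clone followed over the conditions. In that case the KO libraries are not independent, as the main fits take them to be. The KO pairs' differences correlated across genes by 0.346 between pluripotent culture and LIF withdrawal, 0.104 between pluripotent culture and embryoid bodies and 0.13 between the other 2. A replicate block gave 3159 calls over the 3 conditions, 7835, 5793 and 6082 for KO versus WT in the order above, and 108 list calls, 94 of them among the 105. Those not called with the block were primitive streak, extraembryonic endoderm and 2-cell-like genes for the difference in LIF withdrawal, and neuroectoderm for that in embryoid bodies. The others were definitive endoderm and nucleolar genes for KO versus WT after LIF withdrawal, general pluripotency for LIF withdrawal in WT, and NF-kB targets for it in KO, and Ragulator, general pluripotency and definitive endoderm genes for embryoid bodies in WT. Of 246 gene values in the text, 242 kept direction and call under every setting run. Of 105 list calls, 55 did so under every setting but the estimated correlation. On the deposited FPKM scale the median log2 fold change of all genes was -0.11 for KO versus WT in pluripotent culture and 0.10 for the difference in embryoid bodies, against -0.01 and 0.04 with TMM scaling. At 10147277 to 10863845 counts per library, 13.5% to 66.7% of the 1.5-fold changes were called in the simulated data.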

Other observations

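Several imprinted genes, which are expressed from 1 parental copy, differed between KO and WT over the 3 conditions, and Plagl1, Meg3 and Rian among them were chosen after their values were seen. Mest, an imprinted gene of the mesoderm, was at 3.13 FPKM in WT pluripotent cells, 3.60 FPKM after LIF withdrawal and 4.01 FPKM in embryoid bodies. In KO it was at 28.0 and 18.6 FPKM, 42.7 and 25.6 FPKM and 36.6 and 24.9 FPKM, a change over the 3 conditions of 3.09 ± 0.27. Plagl1, a zinc-finger factor, changed by 3.07 ± 0.38, and the long noncoding RNAs Meg3 and Rian of the imprinted Dlk1-Dio3 region by 2.47 ± 0.46 and 2.49 ± 0.44. Dlk1 itself fell by 1.79 ± 0.18 on the log2 scale. Impact rose by 1.52 ± 0.18, and Peg3 fell by 2.09 ± 0.15 on the log2 scale. Meg3 was at 0.51, 0.95 and 1.19 FPKM in the WT libraries and at 5.95 and 3.47, 3.02 and 1.89 and 10.8 and 4.51 FPKM in the KO libraries, in the same order of conditions, and after LIF withdrawal alone its difference did not pass (adjusted p = 0.0717). For Mest, Plagl1, Meg3 and Rian, KO replicate 1 lay above KO replicate 2 in all 3 conditions.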
